A study of Camellia oleifera with 24 samples.

How the data were processed

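RNA was measured in kernels, the embryo freed from the seed coat, of Camellia oleifera, a woody crop whose seeds are pressed for edible oil. Kernels of 4 cultivars (Huashuo, Huaxin, Huajin and Jujian) were taken at 3 stages, in June during fruit swelling, in August during rapid storage synthesis and in October at seed maturity. Each of the 12 groups of cultivar and stage had 2 samples, and each of the 24 samples was hybridized to 1 array. Per the labels' protocols, fruit was picked at random from 10 plants of each cultivar, and RNA was amplified and labelled with the dye Cy3. The series' design text calls the second hybridization of each group a biological repeat. Nothing in the labels says which plants gave which sample, so the p-values measure only the spread between the 2 samples of a group, which may be technical in part. The description field of the labels names fruit swelling for all stages, while the title and the stage characteristic give the 3 stages, which were used. The titles call all arrays the first replicate, and the letter A or B in the sample name was taken as the replicate.

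The deposited scanner files hold 1-colour intensity values of a custom Agilent array, per the file headers, read with Feature Extraction 11.5.1.1, whereas the submitters' processing notes name version 10.7. The processed signal in these files is a background-corrected intensity on a linear scale, per the file headers. The deposited files also give a yes or no flag per spot for a signal well above background. The deposited value table of the whole series holds log2 values. It was set against the scanner files for 35020 to 35033 probes per column. In every column, 100% of the entries compared lay within 0.01 of the log2 processed signal minus a constant, and each column's 75th percentile was near 0. It was used as an alternative. Neither the files nor a reference table paired probes with gene names, so transcripts are given by the IDs of the assembly on which the array was built. The 20 lists of genes for oil, storage protein, maturation and other pathways that were fixed before the data were examined could not be made, and no test of gene lists was run.

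Of 61657 spots per array that were not controls, outlier spots were left out and spots of 1 probe were averaged on the log2 scale, which gave 35033 probes. No spot was saturated (0 on every array). For each array the 75th percentile of log2 processed signal was subtracted, with no pseudocount, and the result is called log2 scaled signal here. A probe counted as well above background on an array if any of its spots did, and was tested if it was so on both arrays of at least 1 group, which kept 33948 probes. The number of arrays limits the precision of every value.

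Group means of all 12 groups were fitted together with lmFit and eBayes of limma 3.58.1 in R 4.3.3, so that all comparisons share 1 estimate of the spread with 12 residual degrees of freedom. Stage contrasts were means over the 4 cultivars of the difference within a cultivar. Each cultivar was also set against the mean of the other 3, over all stages. Limma F tests asked whether cultivars differed at all (3 degrees of freedom) and whether stage changes differed among cultivars (6 degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method. A probe was called at an adjusted p under 0.05 and a change of at least 2-fold, or at the adjusted p alone in the F tests. For each stage contrast the 2 largest rises and the 2 largest falls are named, among called probes with 1 direction in all 4 cultivars. For each cultivar the same was done among called probes with 1 direction at all 3 stages, and for the interaction the 2 smallest p-values are named. The rule was written for gene names, with this fallback to IDs. It asked for signal well above background on the brighter side, and here both sides had to be so on every array compared, because values at the floor have no order. Transcripts behind counts of 5 or fewer are named as well, chosen after their values were seen. A probe well above background on all arrays of 1 side and on none of the other is given as a lower bound. The bound sets the mean of the brighter side against the higher of the dim probe's signal and the lowest signal of any probe well above background, on each array of the dim side.

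Each stage was hybridized on 1 slide of 8 arrays, so stage and slide cannot be told apart in any stage comparison. Cultivars were compared within slides, but each cultivar had the same place on all 3 slides, so cultivar and place on the slide cannot be told apart. The fit was tested on simulated data of 33910 probes, with known changes in 100 of them at each size of change. At a simulated log2 change of 1.5, it recovered 83% of changed probes for August against June, 70% for October against August, 83% for October against June, 84% for Huashuo against the other cultivars and 39% for August against June in Huashuo. For the interaction it recovered 4% at a log2 change of 1.5 and 17% at 2, and it called between 2 and 9 unchanged probes in these runs. The simulated noise was normal, with 1 spread per probe in all 12 groups. In the data, the variance of the difference between replicates ran from 0.040 (Huashuo June) to 0.907 (Huashuo August). These rates and counts therefore need not hold for the arrays themselves.

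The comparisons, thresholds, naming rule and alternatives were fixed before the data were examined, apart from those said to be chosen later. The comparisons of 1 cultivar's step with the others' and of cultivars at 1 stage in the joint fit were added after. The alternatives were quantile normalization, scaling by the median, no filter on dim probes, a stricter filter, the deposited value table, a block for the replicate letter, another variance model, array weights, no fold threshold, only the arrays compared, and leaving out each array in turn. For steps within a cultivar, the setting of only the arrays compared used all arrays of that cultivar. Normexp correction had been planned on the mean signal, a column that the files read here lack, and was run on the median signal instead, followed by quantile normalization. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.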

Results

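The 24 arrays measured RNA of Camellia oleifera kernels from 4 cultivars at 3 stages, with 2 samples in each of 12 groups. Between 85.2% and 96.2% of the 35033 probes were well above background on an array. The median processed signal was 2661 to 3821 on the June arrays, 772 to 1800 on the August arrays and 960 to 1530 on the October arrays. Probes well above background on all 8 arrays of a stage numbered 30994 in June, 28034 in August and 28121 in October, and 26773 were so on all 24 arrays. Stage held 47.7% of the sum of squares over all probes, cultivar 18.2% and their interaction 18.2%, and the rest lay between replicates. The replicates of a group correlated across probes at r = 0.943 (Huashuo August) to 0.997 (Huashuo June). The pairs of Huashuo June and Jujian June (r = 0.992) lay closest together. The variance of their differences was 3.54 and 7.67 times that from duplicate spots, against 27.5 and 68.3 in the other June pairs, on the same slide, and 7.07 (Jujian August) to 56.9 (Huaxin October) at the later stages. Duplicate spots leave out noise of labelling and hybridization, so the ratio does not tell whether a pair was 1 RNA measured 2 times. They entered as separate samples because the design text names a biological repeat.

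**Figure D1:**
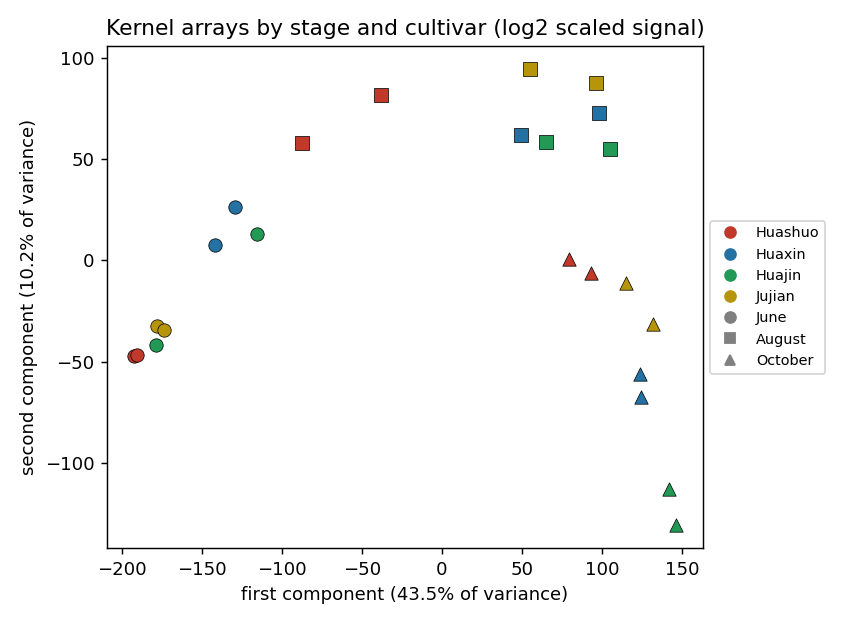
Each point is 1 array on the first 2 principal components of log2 scaled signal, with the percent of variance on each axis, coloured by cultivar and shaped by stage. June arrays lie at the left (first component -192 to -116) and October arrays at the right (79.7 to 146), and the 2 Huashuo August arrays (-87.2 and -37.9) lie apart from the other August arrays (49.3 to 105).

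The title of the series places the stages in the study of tea oil accumulation. Between June and August the transcript comp104363_c3_seq1 rose 122-fold (log2 change 6.93, SE 0.24, limma adjusted p = 2.73e-10), from a log2 scaled signal of -1.32 ± 0.69 (SD, n = 8) to 5.61 ± 0.85 (SD, n = 8), and it stayed at 5.80 ± 0.29 (SD, n = 8) in October. The transcript comp108616_c0_seq1 rose 164-fold (log2 change 7.36, SE 0.65, limma adjusted p = 5.04e-07), and its October level was 3.56 ± 0.26 (SD, n = 8). Its June values were spread widely (-4.36 ± 3.13, SD, n = 8), with a mean of -7.58 in Huashuo and -1.07 in Huaxin. Among the falls, comp115170_c0_seq1 went from 2.86 ± 0.43 (SD, n = 8) to -4.21 ± 2.29 (SD, n = 8), a log2 change of -7.07 (SE 0.43, limma adjusted p = 1.75e-08). The signal of comp100357_c0_seq1 went from 3.36 ± 0.19 (SD, n = 8) to -3.04 ± 3.01 (SD, n = 8), a log2 change of -6.40 (SE 0.39, limma adjusted p = 1.95e-08). In both, the August mean of Huashuo stood above that of the other cultivars.

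In all, 8416 probes were called between June and August, of which 2874 were higher and 5542 lower in August. Changes of at least 4-fold were seen in 3040 of them, 829 upward and 2211 downward, and changes of at least 16-fold in 600, 205 upward and 395 downward. The direction was the same in all 4 cultivars for 7202 of the 8416 probes (85.6%). Tested in each cultivar alone, 461 probes were called higher in all 4 and 1141 lower in all 4, against 2.50 and 13.5 if the 4 lists were independent. The share of called probes that were higher depended on the scaling. It was 34.1% here and 47.3% after quantile normalization, which called 4019 higher and 4474 lower. Among probes well above background on all 24 arrays, 5480 were called.

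**Figure D2:**
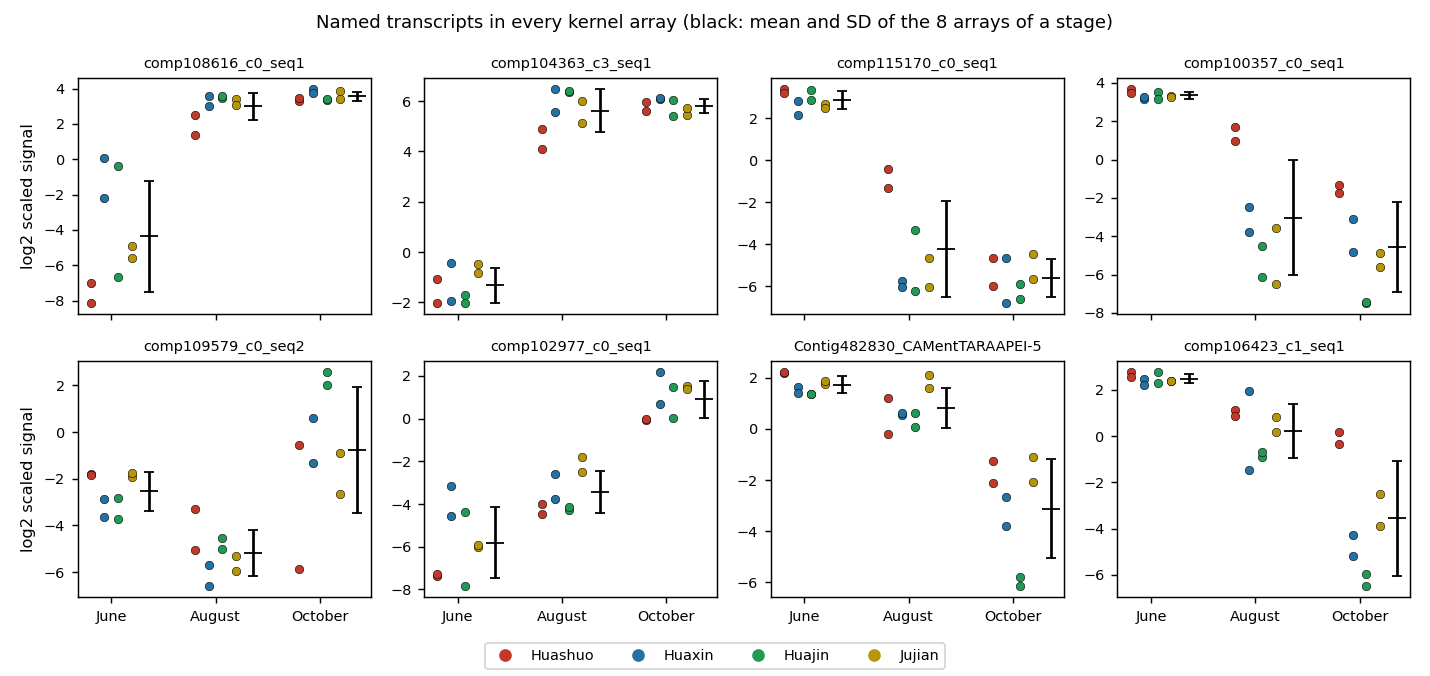
Each panel shows 1 transcript named for a stage change, with the log2 scaled signal of every array by stage, coloured by cultivar, and a black mark and bar for the mean and SD of the 8 arrays of the stage. The top row holds the transcripts named for June to August (log2 changes 7.36, 6.93, -7.07 and -6.40 from left to right), and the bottom row those for August to October (4.42, 4.35, -3.94 and -3.79).

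From August to October the changes were smaller. The transcript comp109579_c0_seq2 rose 21.4-fold (log2 change 4.42, SE 0.60, limma adjusted p = 5.47e-05), to -0.77 ± 2.70 (SD, n = 8) in October, and its June level was -2.55 ± 0.84 (SD, n = 8). Its October mean was -3.23 in Huashuo and 2.30 in Huajin. The Huashuo mean joins unlike arrays, at -0.57 and -5.88, where the Huashuo August arrays stood at -5.1 and -3.3. The transcript comp102977_c0_seq1 rose 20.3-fold (log2 change 4.35, SE 0.43, limma adjusted p = 3.9e-06) and reached 0.91 ± 0.85 (SD, n = 8) in October. Contig482830_CAMentTARAAPEI-5 and comp106423_c1_seq1 fell by 3.94 and 3.79 on the log2 scale, with October levels of -3.12 ± 1.95 (SD, n = 8) and -3.56 ± 2.49 (SD, n = 8). In October, comp106423_c1_seq1 stood at -0.07 in Huashuo and -6.24 in Huajin.

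Between August and October 5407 probes were called, 2332 higher and 3075 lower, and 1004 of them changed at least 4-fold. After quantile normalization 2485 were higher and 2478 lower. The direction was shared by all 4 cultivars for 4430 of the 5407 (81.9%). By the contrasts within each cultivar, 260 were called higher in all 4 and 176 lower in all 4, against 0.575 and 0.724 if the lists were independent, which they again are not. The count was 3542 among probes well above background on all arrays and 3588 after normexp correction of the median signal together with quantile normalization, which alone gave 4963. October against June gave 10874 called probes, 4058 higher and 6816 lower, and 1139 of them changed at least 16-fold. The share of these that were higher was 37.3%, and 51.5% after quantile normalization, which called 5566 higher and 5246 lower.

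Both steps together sorted the probes by their course. 1112 probes fell at both steps, 260 rose at both, 716 fell and then rose, and 315 rose and then fell. Independent lists of the same lengths would share 502, 197, 381 and 260 probes. Both steps use the August arrays, whose noise enters them with opposite sign. With replicate 1 of August in the first step and replicate 2 in the second, 1414 probes fell at both steps, 377 rose at both, 571 fell and then rose, and 239 rose and then fell, the last below the 315 that independence gives. With the replicates exchanged these counts were 1035, 204, 679 and 273, the last above the 239.5 that independence gives. A further 6013 probes were called in the first step alone and 3004 in the second alone.

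Some probes passed in or out of detection. 196 probes were well above background on all 8 June arrays and on none of the 8 October arrays, at least 3.48-fold higher in June at the median and up to at least 523-fold. All 196 had a limma adjusted p under 0.05. For 55 probes, June was above background on all 8 arrays and August on none, at least 1.55-fold higher in June at the median, and 54 of them had a limma adjusted p under 0.05. Only 2 probes were above background on every October array and no June array, comp81466_c0_seq2 and Contig478252_CAMentTARAAPEI-5, at least 12.5-fold higher in October at the median.

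The same steps were compared within each cultivar, with 2 arrays against 2 and the spread of the joint fit. June to August gave 6886 called probes in Huashuo (2116 higher, 4770 lower), 7301 in Huaxin (3278 and 4023), 8733 in Huajin (4131 and 4602) and 9402 in Jujian (3419 and 5983). August to October gave 6537 in Huashuo (3609 higher, 2928 lower), 3393 in Huaxin (1529 and 1864), 6856 in Huajin (2931 and 3925) and 2714 in Jujian (1392 and 1322). Quantile normalization turned the balance from June to August in Huaxin (4211 higher, 3497 lower), Huajin (5027 and 4300) and Jujian (4971 and 4634), and from August to October in Huajin (3355 and 2900). It called 2789 higher and 3758 lower from June to August in Huashuo. Scaling by the median turned the first step in Huaxin (4090 and 3563) and the second in Jujian (1279 and 1478), and gave 4497 higher and 5040 lower for the first step in Jujian. Several of these counts rest on single arrays. The first step fell to 3193 in Huashuo without its June replicate 2 and 4044 without its June replicate 1, to 3871 in Huaxin without its August replicate 1, and to 5086 in Huajin without its June replicate 1. The second step fell to 3891 and 3949 in Huashuo without its August replicate 2 or October replicate 1, to 1786 in Huaxin without its October replicate 1, and to 3998 in Huajin without its October replicate 2. In Jujian the second step fell to 1382, 1713 and 1433 without August replicate 1, October replicate 1 or October replicate 2. The counts also rest on the spread of the joint fit. When each cultivar's own arrays alone set the spread, the second step gave 391 in Huaxin and 3613 in Huajin, and the first 4006 in Huaxin. The other counts of these steps then lay within 1.5 times of those reported.

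**Figure D3:**
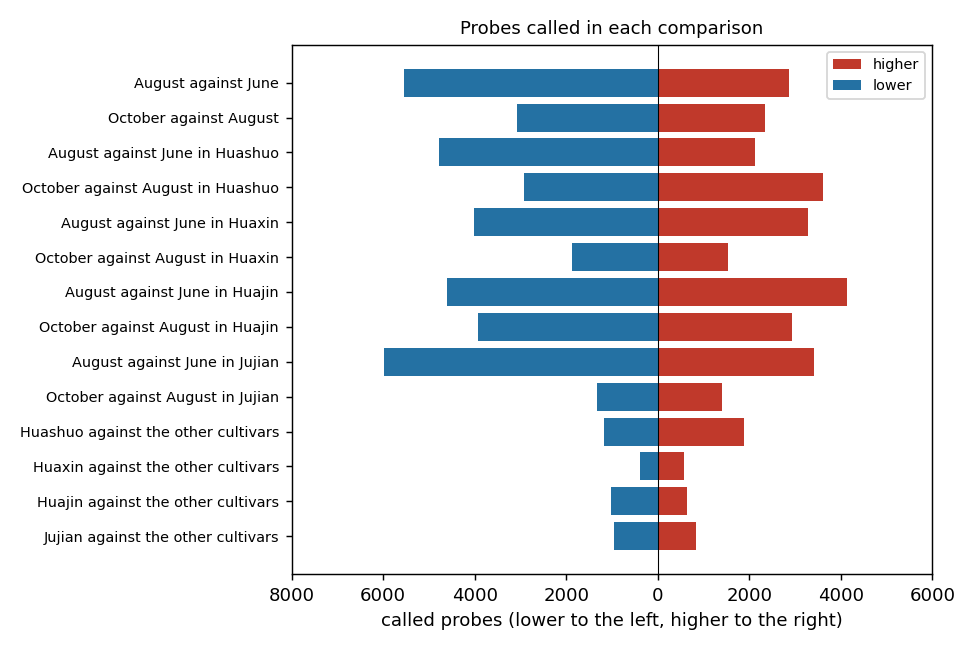
Bars give the number of probes called higher (right) and lower (left) in each comparison, for the stage steps over all cultivars, the steps within each cultivar, and each cultivar against the other 3. The longest bar is the 5983 probes lower in August than in June in Jujian.

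Whether cultivars took the same steps was tested directly. The transcript comp105384_c0_seq27, well above background on all 24 arrays, had among the smallest interaction p-values (limma adjusted p = 7.93e-05). From August to October it went from -0.24 to -3.76 in Huaxin and from -0.22 to -4.32 in Huajin (means of 2 arrays, SD between 0.06 and 0.17), whereas in Huashuo it was -0.03 in August and 0.02 in October. The other, comp102528_c1_seq18, was well above background on 12 arrays only. In total 6653 probes had stage changes that differed among cultivars. The counts were highest for Huashuo. Its step from June to August differed from the mean of the other 3 cultivars for 4837 probes and its step from August to October for 3783. The same counts were 213 and 4 in Huaxin, 661 and 1818 in Huajin, and 1191 and 150 in Jujian. The 4 in Huaxin were comp87842_c0_seq1 (log2 difference of steps 3.09, limma adjusted p = 0.0336), comp106804_c0_seq1 (2.58, 0.0234), comp103213_c2_seq1 (-3.32, 0.0451) and comp111765_c0_seq18 (-4.86, 0.0178). This count was not stable: it was 9 with quantile normalization, 2 with array weights and 1 among probes well above background on all arrays. Across probes, the June to August changes of Huashuo correlated with those of the other cultivars at r = 0.416 to 0.601, and those of the other 3 among themselves at 0.684 to 0.78. Probes are not independent replicates.

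These interaction counts lean on the close June pairs. With the arrays of Huashuo June and of Jujian June each averaged to 1 sample, a setting chosen after seeing the data, the counts were 907 for the interaction and 518 for a different June to August step in Huashuo. Array weights, which favoured these pairs, gave 11145 for the interaction. With them, a different first step was called for 2153 probes in Jujian, but for 26 in Huaxin and 252 in Huajin. A different second step was called for 1930 in Huashuo, 21 in Jujian and 2 in Huaxin. Without a single array of these pairs the interaction gave 2875 to 3689 probes. The different first step of Huashuo was called for 2000 and 1068 probes without its June replicate 1 or 2 and for 1889 without its August replicate 2. Its different second step was called for 1387, 5934, 1493 and 1820 without August replicate 2, August replicate 1, October replicate 1 or October replicate 2.

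Averaged over the stages, 12151 probes differed among the cultivars by the limma F test. Huashuo had the most probes apart from the other 3 (3067 called, 1893 higher and 1174 lower), followed by Jujian (1786, 831 and 955), Huajin (1659, 634 and 1025) and Huaxin (945, 565 and 380). With no fold threshold the balance turned in Huashuo (4117 higher, 4437 lower) and Jujian (3122 and 2161). The order depended on August: without the August arrays, a setting chosen after seeing the data, Huajin gave 2369, Huashuo 2260, Jujian 2010 and Huaxin 944. Of the 3067 probes of Huashuo, 52.3% were also called there and 60 had the opposite sign. The sign was the same at all 3 stages for 82.8% of the called probes in Huashuo, 89.3% in Huaxin, 83.7% in Huajin and 88.5% in Jujian.

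In Huashuo, Contig483702_CAMentTARAAPEI-5 was 24.1-fold higher than in the other cultivars (log2 difference 4.59, SE 0.31, limma adjusted p = 7.22e-07), and the difference was 1.76 in June, 5.50 in August and 6.51 in October. The difference of comp87168_c0_seq1 was 4.41 (SE 0.28, limma adjusted p = 5.44e-07). On the lower side, comp99824_c0_seq1 differed by -4.28 (SE 0.71, limma adjusted p = 0.00102) and comp108216_c0_seq2 by -3.84 (SE 0.31, limma adjusted p = 3.41e-06). The former was also among the highest of Huaxin against the rest (log2 difference 3.74, SE 0.71, limma adjusted p = 0.00742), and in Huashuo the difference was -5.89 in June, -1.92 in August and -5.02 in October. In October, comp108216_c0_seq2 was lower in Huajin (-3.77) than in Huashuo (-2.77).

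Huaxin was highest above the rest in comp114446_c2_seq1 (log2 difference 4.08, SE 0.66), at 4.43, 4.31 and 3.48 in June, August and October. Its lowest were comp102462_c0_seq5 and comp102462_c0_seq3, transcripts of 1 assembled component, at -3.20 and -3.06. Huajin was higher in comp96824_c0_seq1 (3.58) and Contig477033_CAMentTARAAPEI-5 (3.56), and the latter differed by 6.62 in June and 0.13 in October. Jujian stood above Huajin in the former in August (1.56 against 0.37) and in the latter in October (-4.11 against -5.25). Huajin was lower in comp106106_c0_seq1 by nearly the same amount at each stage (-3.42, -3.48 and -3.33) and in comp110942_c1_seq1 (-3.04). Huaxin was nearly as low as Huajin in comp110942_c1_seq1 in June (-4.72 against -5.09) and August (-4.6 against -4.7), but not in October (-2.12 against -4.43). Jujian was higher in comp104123_c0_seq3 (3.93) and comp114001_c1_seq1 (3.77), and lower in comp95999_c0_seq2 (-3.68) and comp104684_c1_seq1 (-3.18). All of these were called by limma at an adjusted p of at most 0.0205. The call of comp96824_c0_seq1 was lost without Huajin June replicate 1, August replicate 1 or October replicate 2 (adjusted p = 0.0507, 0.0699 and 0.084) and with the 2 close June pairs averaged (0.0532).

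Detection separated the cultivars in few cases. At every stage, 2 probes were above background in Huashuo alone, comp439873_c0_seq1 (at least 11.2-fold higher) and comp92221_c0_seq1 (at least 6.72-fold). The probe of comp102155_c3_seq1 was above background on all arrays of the other cultivars and none of Jujian, at least 12.6-fold lower there. No probe set Huaxin or Huajin apart in this way.

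Since each slide held 1 stage, the cultivars were also compared on each slide alone, with 8 arrays. Each such fit takes its spread from the pairs on its own slide. On the June slide these include the close pairs of Huashuo and Jujian. The variance of their differences was 0.040 and 0.089, against 0.540 (Jujian) to 0.907 (Huashuo) on the August slide. Counts of different slides therefore cannot be ranked against each other. Huashuo gave 2766 called probes on the June slide, 3437 on the August slide and 1058 on the October slide. The other cultivars gave 2203 (Huaxin), 2644 (Huajin) and 3737 (Jujian) on the June slide and 1, 23 and 35 on the August slide. On the October slide they gave 1 (Huaxin), 2515 (Huajin) and 90 (Jujian). The single probes of Huaxin were comp597234_c0_seq1 in August (log2 difference 3.71, limma adjusted p = 0.0421) and comp114774_c0_seq1 in October (3.24, limma adjusted p = 0.0222).

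The joint fit of all 24 arrays, which shares the spread of all groups, gave other counts for the same comparisons. Its F tests of differences among cultivars at 1 stage called 4698 probes in June, 10478 in August and 5440 in October. The joint fit gives all groups 1 spread, although their pairs differed unequally, so this order is not secure either. In June, August and October it called 1367, 7443 and 1905 probes for Huashuo, 1097, 553 and 348 for Huaxin, 834, 1268 and 3455 for Huajin, and 2092, 1669 and 722 for Jujian. With 1 array left out at a time these ranged from 142 to 2153, 2759 to 9024 and 318 to 2205 for Huashuo, and from 155 to 1787, 159 to 1116 and 138 to 773 for Huaxin. For Huajin they ranged from 443 to 1056, 232 to 1908 and 1160 to 3743, and for Jujian from 335 to 2365, 208 to 2655 and 130 to 869. The lowest count came without an array of the cultivar at that stage, except for Huajin in June (without Huashuo June replicate 2).

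The number of probes that set cultivars apart varied with other choices. The F test gave 12616 with quantile normalization and 12985 when normexp correction of the median signal was added to it. Among probes well above background on all arrays, Huashuo, Huaxin, Huajin and Jujian against the others gave 1471, 484, 730 and 921. With normexp correction and quantile normalization together, Huashuo gave 2019, Huajin 1003 and Jujian 1169, and with the 2 close June pairs averaged the F test gave 5329. Without Huaxin June replicate 1, Huaxin gave 596, and without Jujian June replicate 1, Jujian gave 1150.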

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

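The scale between June and October with its 7 versions, the tests of single steps, the test of the split between higher and lower probes, the limit set by falling probes and, in the component test, the interval and the part on mismatch of the called probe alone were chosen only after results were seen.

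Stage changes differed among cultivars for 6653 probes by the limma F test. A single cultivar's step differed from the mean of the other 3 for 4837 probes (June to August) and 3783 (August to October) in Huashuo, 213 and 4 in Huaxin, 661 and 1818 in Huajin, and 1191 and 150 in Jujian. With 1 array left out at a time, the first step ranged from 1068 to 6871 in Huashuo, 16 to 990 in Huaxin and 158 to 1720 in Jujian, and reached 1582 in Huajin, where the count without Huajin August replicate 1 was 5.37 times smaller than 661. The second ranged from 1387 to 5934 in Huashuo, 498 to 2821 in Huajin and 22 to 315 in Jujian, and reached 255 in Huaxin. With the close June pairs averaged, the first step gave 518 in Huashuo, 14 in Huaxin, 63 in Huajin and 77 in Jujian, and the second 2345 in Huashuo, 821 in Huajin and 16 in Jujian. In Huaxin the calls of a different second step were lost with these pairs averaged and in some of the fits with 1 array left out. Among 37 sets of values over the 8 arrays of a stage that were examined for a lone array, 1 had one. On Huajin June replicate 1, 90.3% of probes were well above background, and the next array had 93.6%. Chance alone gives such an array in about 1 of 20 sets.

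The Huashuo August arrays lay nearer to June than the other August arrays. The scale put each cultivar's own June at 0 and own October at 1, over 10865 probes. On it the Huashuo August arrays stood at 0.566 and 0.44 and the other 6 between 0.591 and 0.849. No version of this scale passed an exact permutation test over 105 partitions of the August arrays into pairs (p = 0.143, and 0.0571 to 0.333 over the 7 versions). That test asks whether arrays of a cultivar lie close together, in any cultivar. It cannot decide whether Huashuo lay nearer to June, and the position of the Huashuo arrays has no p-value here. The cultivar profile of both arrays correlated best with Huashuo at the other stages (r of at least 0.243). This argues against a wrong cultivar label only if place on the slide did not make the match. Huashuo had the same place on every slide, so the profiles cannot tell these apart. June RNA mixed into the samples is argued against as the whole source, since sets of probes would need June shares that spread by 0.542 (0.222 to 0.764), and a mixture could not exceed the ratio of Huashuo August to June signal in probes that fell in the other cultivars (median 0.371, 10th percentile 0.1). Quantile values alone left the difference at -0.21 (-0.22 before), but array brightness stays open, since the 2717 brightest probes (-0.15, and with quantile values 0.587 of the full size) no longer separated the arrays, as does the place on the slide, since the gap of 0.0244 was under the largest difference between replicates (0.173); on the other cultivars' axis, which does not remove an effect of place, the gap was 0.276 against 0.152. A later course of ripening in Huashuo could also give this position and was not tested apart from these.

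More probes were lower than higher after June, and detection was lost more often than gained. For the split of called probes, the brightness of the June slide stays open. Quantile normalization brought the share that was higher in October to 51.5%, but it gives all arrays 1 distribution and would do so whether slide or kernels made the difference. For the 196 probes detected in June and in no October array brightness is argued against, since 97.4% of them had a June level above the level at which October arrays detect nearly every probe (77.6% after quantile normalization). Stage and slide cannot be told apart, so other effects of the slide stay open beside a change of the kernels.

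Probes that differed among cultivars might do so because a cultivar's sequence mismatches the probe. For each called probe, the other transcripts of the same assembled component, each with its own probe, were averaged. The median of their differences, in the direction of the called probe, was 67.2% of the median of the called probes in Huashuo (95% bootstrap interval over components 61.9 to 70.3). This ratio of medians was 60.9% in Huajin (55 to 69.5), 66.0% in Jujian (57.9 to 73.5) and 51.4% in Huaxin (46.3 to 57.7). Mismatch of the called probe alone is argued against as the whole source in Huashuo, Huajin and Jujian, where the intervals lie above the 50% set beforehand (at least 55). In Huaxin the value passed 50% but its interval, added once the value was known, does not, so mismatch stays open there. Mismatch in a stretch that transcripts of a component share would lower all their probes and meet the same bound, so in every cultivar it cannot be told apart from expression.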

How the results depend on the processing

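Normexp on the median signal, the averaged June pairs, and the fits without Huashuo or without August were chosen after the results were seen, as were the comparisons of 1 cultivar's step with the others' and of 1 cultivar at 1 stage. Over 611 counts of the stage, cultivar and interaction comparisons under another setting, 564 lay within 1.5 times of the reported one and 47 did not. The steps of 1 cultivar against the others moved by over 1.5 times in 94 of 280 such counts, and the counts of 1 cultivar at 1 stage in 72 of 420. Of 913 reruns of named transcripts, 909 kept the call, 4 kept direction only (all of comp96824_c0_seq1) and 0 reversed. These transcripts were picked as the strongest calls in the same arrays, so this is no independent check. Interaction F tests have no direction. Where no construction of the setting shows why a count moved, the cause was not tested.

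With only probes well above background on all arrays, fewer probes were tested, and August against June gave 5480, October against August 3542, and Huashuo, Huaxin, Huajin and Jujian against the others 1471, 484, 730 and 921. Normexp on the median signal with quantile normalization gave 3588 for October against August and 2019, 1003 and 1169 for Huashuo, Huajin and Jujian against the others. With no fold threshold the counts were 18781 (August against June), 14621 (October against August), 21136 (October against June), 8554 (Huashuo), 2287 (Huaxin), 4242 (Huajin) and 5283 (Jujian). Array weights gave 1636 for October against August in Huaxin and 11145 for the interaction, with weights from 0.422 (Huashuo August) to 6.96 (Huashuo June). Fitted on the 6 arrays of the cultivar alone, and so with fewer samples, Huaxin gave 4006 and 391 at its 2 steps, and Huajin 3613 at its second.

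With the Huashuo June and Jujian June pairs each averaged, fewer samples enter and the counts were 2727 (August against June in Huashuo), 5707 (the same in Jujian), 1765 (October against August in Jujian), 2019, 575 and 850 (Huashuo, Huaxin and Jujian against the others), 5329 (differences among cultivars) and 907 (interaction). Without the Huashuo cultivar, August against June gave 9374, October against August 5408 and October against June 11062. Without the August arrays, Huashuo, Huaxin, Huajin and Jujian against the others gave 2260, 944, 2369 and 2010.

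Leaving out each array in turn, a lone array being assumed to vary like the other groups, gave 8061 to 8916 for August against June, 5136 to 5591 for October against August and 10690 to 11039 for October against June. The first step ranged from 3193 to 7041 in Huashuo, 3871 to 8179 in Huaxin, 5086 to 9053 in Huajin and 6445 to 9687 in Jujian, and the second from 3891 to 7800, 1786 to 3706, 3998 to 7245 and 1382 to 3022. Against the others, Huashuo ranged from 2329 to 3794, Huaxin from 596 to 1243, Huajin from 1369 to 1806 and Jujian from 1150 to 2048. Differences among cultivars ranged from 8311 to 14113 and the interaction from 2875 to 8976.

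No general pairing of samples by replicate letter was seen: over 66 pairs of groups, deviations of like-lettered arrays correlated at -0.26 to 0.25 (median 0.01). The correlation was over 0.1 in 7 pairs. Groups of the same cultivar were not examined apart, so a pairing within a cultivar stays open. With a replicate block the counts were 8407 (August against June), 5398 (October against August), 10888 (October against June), 11646 (differences among cultivars) and 5715 (interaction), and the count for the first step of Huaxin against the others went from 213 to 101. The slide could not enter as a block because it holds 1 stage only, normexp on the mean signal was not run, and no gene list could be tested. Quantile normalization moved the median log2 change of all probes from -0.03 to 0.14 for October against June. The share of called probes that were higher went from 34.1% to 47.3% for August against June and from 37.3% to 51.5% for October against June, and with normexp added to quantile normalization to 44.3% and 48.6%. For October against August it went from 43.1% to 50.1% with quantile normalization. Lower signal over background in August and October limits what can be seen of dim probes there.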

Other observations

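The correlations of steps between cultivars were chosen after the data were seen.

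Transcripts of 1 assembled component moved together. The array held 4914 components with at least 2 tested probes, 21903 probes in all. Of 15380 pairs of such transcripts both called between June and October, 96.3% changed the same way, against 55.6% among random pairs, in line with the prediction made for transcripts that share their stage change. For probes called between June and August, the other transcripts of the component had a median change of 1.20 in the same direction (log2), against 1.61 for the called probes, and 61.6% of them were called the same way and 1.93% the opposite way. Pairs that share a component share sequence, so their probes may bind each other's transcripts, and the 96.3% is no count of independent genes.

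Relatedness among the cultivars' courses was uneven. From June to August, Huaxin and Huajin correlated most across probes (r = 0.78) and Huashuo and Huaxin least (0.416). From August to October, the same pairs gave 0.593 and 0.335, and Huashuo and Huajin gave 0.246. Each array's cultivar profile, its deviation from the mean of its stage, was set against the profiles at both other stages, and its own cultivar fitted best in 45 of 48 comparisons. The exceptions were Huajin June replicate 1 (r = 0.0851 against 0.109 for Huashuo), Huajin August replicate 1 (0.0647 against 0.0904 for Jujian) and Huaxin October replicate 2 (0.0807 against 0.11 for Huajin). Each cultivar had the same place on every slide, so an effect of place could also make the profiles match.

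The 2 June arrays of Huajin lay apart in some values, although their correlation (r = 0.946) was no lower than that of Huashuo August (0.943). Whether kernels or handling differed was not tested. Huajin June replicate 2 lay at -116 on the first principal component and replicate 1 at -178, and their log2 scaled signals of comp108616_c0_seq1 were -0.40 and -6.69.

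Chance alone is argued against as the source of the stage and cultivar counts, if the 2 arrays of a group are independent samples. A split that mixes unlike groups puts their difference into the spread, which lowers its count. Arrays that differ by slide or by place on the slide would give the same outcome, so the splits do not bear on these. Of 100 splits each that exchanged stages among arrays of a cultivar, 1 (the real one) gave as many called probes for August against June (8416, the highest of the others 6844), for October against August (5407, highest other 3019) and for October against June (10874, highest other 7505). Of 100 splits that exchanged cultivars among the arrays of a stage, again only the real 1 reached the counts for differences among cultivars (12151, highest other 289), Huashuo (3067, highest other 188), Huaxin (945, highest other 555), Huajin (1659, highest other 753) and Jujian (1786, highest other 237). If a close June pair was 1 RNA measured 2 times, splits that part it hold more spread than the real one and the comparison is too favourable. Splits close to the real one, which exchange few arrays, keep much of its difference.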
